A study of Homo sapiens with 12 samples.

How the data were processed

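The labels describe 12 libraries, 3 each of Si and NC in the glioblastoma lines U251 and T98G. The 6 U251 libraries were analysed, and the 6 T98G libraries were not analysed here. Groups and replicate numbers come from the sample titles. The titles say Si and NC only; the design text of the series speaks of wild-type and NSUN3-knockdown cells, and Si was read as the knockdown. Nothing in the labels says that replicates came from separate cultures, so the spread between these libraries may be technical. The p-values cover only that spread and counting error.

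Per the labels' protocols, RNA was taken up in TRIzol, small RNA was enriched and treated with AlkB, a demethylase that removes base methylations which stop reverse transcription, then converted with bisulfite and made into small RNA libraries selected for the size of tRNA fragments. The submitters' processing notes name cutadapt 1.9.3 and the build hg38. The aligner, the site caller, its filters and the handling of duplicate reads are not given in the sources used here. An incomplete conversion leaves unmodified cytosines that look methylated, and cytosines with other modifications that resist bisulfite cannot be told from methylated ones.

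Per the file headers, the authors deposited for each library a list of sites with 3 counts: the reads over the site, the reads with an unconverted cytosine, and the reads with another base. The authors also gave the methylation level as a fraction; recomputed from the counts it is the unconverted reads over the coverage less reads with another base, of which the lists hold 1. The deposited adjusted p-value of each site for being methylated was 0.0001 or lower, when rounded, in the lists, its method is not given in the sources used here, and it entered no test. The lists begin at a coverage of 30 reads and a level of 10.0%, so the lists are filtered and the full depth of a library is unknown. With 30 to 210 reads per site, single-library levels have wide counting errors. At tRNA-iMet-CAT-1-1 position 48, exact binomial 95% intervals ran from 75.5% to 86.7% in NC replicate 1 and from 55.7% to 75.8% in Si replicate 1. Intervals cover counting error only, since reads without molecular identifiers need not be independent molecules.

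Standard positions were assigned from each tRNA's own sequence, with the anticodon at 34 to 36 and bases from 49 to 73 counted back from the 3′ end; tRNA-SeC and bases that this does not number are given by the base counted from the 5′ end. All 15 tRNA genes matched a gene of the RefSeq table of assembly GRCh38.p14 by chromosome, start and end. Neighbouring sites share reads, and near-identical tRNAs, such as tRNA-Gly-GCC-1-1 and tRNA-Gly-GCC-2-1 or tRNA-Thr-CGT-2-1 and tRNA-Thr-CGT-4-1, can share or divide reads in ways that the lists do not show, so their levels and coverage are uncertain to that extent.

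Sites listed with at least 10 reads in at least 2 libraries of each group were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest) on methylated and unmethylated counts with an intercept per library, Benjamini-Hochberg adjustment over the 31 sites and a threshold of 0.05. That the dispersion was estimated without a trend was a detail chosen later. limma 3.58.1 was run on log2 ratios of methylated to unmethylated reads with 1 added to each. Means over sites, classes and numbers of listed sites were compared by exact two-sided permutation tests in scipy 1.17.1, with pandas 2.3.3, numpy 2.4.6 and Python 3.11.15. The tests, classes, alternatives and the rule for named sites were fixed before the data were examined, with some exceptions chosen after seeing the data. These were the coverage comparison per tRNA with all its settings, the minimum of 40 reads and the test of the fixed classes only. The block for class means and the tests of flagged results and of explanations in the additional observations were also chosen then.

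The rule named mitochondrial tRNA sites, of which none was listed; tested members of the position 34, 38, 40 and 72 classes, at most 10 by coverage; sites past the threshold whose groups do not overlap, filled up to 10 with the smallest p; the 5 tested sites with the highest mean level in NC; and at most 5 sites per direction listed in every library of 1 group and none of the other. This gave 19 sites, 15 of them tested. The sites plotted include tRNA-His-GTG-1-4 position 30, which was chosen after its values were seen.

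The per-site test was checked on simulated reads with the real coverage of the 31 sites, 5 changed sites and 30 simulations per size. It recovered 6.7% of the sites changed by a log2 odds ratio of 1 and 45.3% of those changed by 2. False calls averaged 0.067 per simulation (in 2 of 30) and 0.133 (in 4 of 30) at these sizes, and 0 when nothing was changed. The simulated spread between libraries was set by hand, so these shares are a guide. At this spread, changes by a log2 odds ratio of 1 were mostly missed, as an average over sites of differing coverage. The tRNA-iMet site showed no spread within groups beyond counting error (chi-square p = 0.880 in NC and 0.593 in Si). The simulated spread adds to counting error, so it may be too wide for that site and its share of recovered changes too low. The shares therefore do not give the power at the tRNA-iMet site.

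Replicates were compared for duplicates. Between 0 and 1 site had identical counts in a pair of libraries of 1 group, and the pairs differed in listed sites, so each library was counted as 1 sample. Chi-square tests of the coverage of 9 tRNAs found no difference in any pair within a group, with p from 0.357 for NC replicates 1 and 3 to 0.980 for NC replicates 1 and 2. Levels over the 21 shared sites differed between NC replicates 1 and 3 (chi-square p = 0.0133, unadjusted over 6 pairs) and not in the other pairs, the lowest p there being 0.232. A large part of that difference came from position 30 of tRNA-His-GTG-1-4, with 47 of 105 reads methylated in NC replicate 1 and 9 of 71 in NC replicate 3. NC replicates 1 and 2 agreed within sampling noise on both counts, but they listed 47 and 34 sites and none with identical counts.

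Coverage per tRNA was compared after the data were seen. The site of highest coverage listed in all 6 libraries stood for each of 9 tRNAs, and libraries were scaled by their geometric mean over these tRNAs. It was first run with limma and then with edgeR, which became the main test because it is made for counts. On simulated counts with 3 of 9 tRNAs changed by a log2 ratio of 1 it recovered 86.7%, with a mean of 0.433 false calls per simulation, against 0.033 when nothing was changed. With so few tRNAs a change in some shifts the scale of the rest. The test of library-wide conversion given among the observations replaced an earlier bound on the lowest listed levels, whose outcome hung on the error multiplier chosen.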

Results

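Cytosine methylation of transfer RNA was measured by bisulfite sequencing in U251 cells, an established human glioblastoma line. Bisulfite turns unmodified cytosine into a base read as T, so a cytosine that is still read as C counts as methylated. The libraries carry the labels Si and NC, with 3 of each. The series' design text names wild-type cells and cells with a knockdown of NSUN3, and Si was read here as the knockdown. NSUN3 is the RNA methyltransferase known to act on the wobble cytosine of the mitochondrial tRNA-Met. The 6 libraries of T98G, a second glioblastoma line, were not analysed here.

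The files listed 59 cytosines in 15 nuclear-encoded tRNAs, and 21 of these sites, in 9 tRNAs, were listed in all 6 libraries. Coverage at a listed site ran from 30 to 210 reads and the methylation level from 10.0% to 98.6%. Since no entry fell below 30 reads or 10.0%, a site that is missing from a library has an unknown level there and was not counted as unmethylated. The Si libraries listed 39, 38 and 38 sites with a summed coverage of 2531, 2292 and 2245 reads, and the NC libraries 47, 34 and 38 sites with 2869, 2020 and 2381 reads. These sums cover listed sites and are not library sizes. Positions are standard tRNA numbers, and coordinates are on hg38.

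The knocked-down enzyme's own target could not be read. No site of a mitochondrial tRNA was listed in any library, and neither was a cytosine at position 34 of any tRNA. The mitochondrial tRNA-Met therefore gives no check of the labels, and the level of the NSUN3 transcript was not measured in this assay.

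Positions 48 to 50, where the variable loop meets the T stem and which are known as sites of the methyltransferase NSUN2, held 27 of the 59 sites. The highest mean level among the tested sites in the NC libraries belonged to tRNA-Glu-TTC-2-1 position 49, at 96.9% ± 1.73 (SD, n = 3), and it was 97.5% ± 1.75 (SD, n = 3) in Si. Position 50 of that tRNA stood at 93.8% ± 3.06 in NC and 91.7% ± 1.31 in Si. tRNA-Gly-CCC-1-1 had 90.7% ± 5.07 at position 49 and 90.7% ± 5.94 at position 50 in NC (SD, n = 3), beside 88.7% ± 5.70 (SD, n = 3) and 88.2% ± 4.55 (SD, n = 2) in Si. tRNA-Gly-GCC-1-1 position 49 had 91.4% ± 2.69 in NC and 94.5% ± 2.20 in Si (SD, n = 3). None of these differences passed the test described next. Coverage at these sites was 32 to 73 reads.

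**Figure D1:**
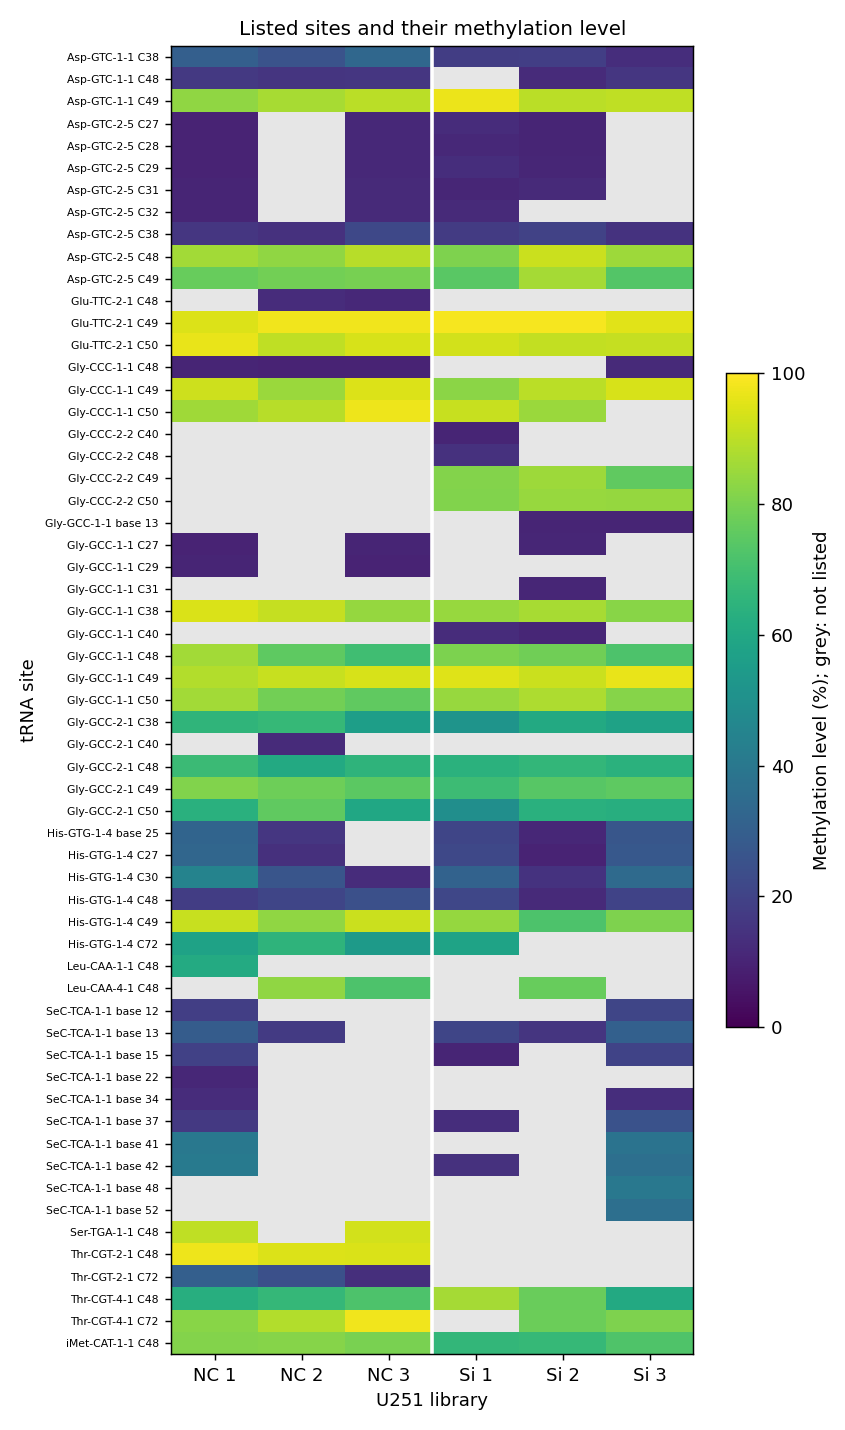
Methylation level in percent (colour) of the 59 listed tRNA sites (rows) in the 3 NC and 3 Si libraries of U251 cells (columns), with unlisted entries in grey. Rows are named by tRNA and standard position, or by the base counted from the 5′ end where no standard number was assigned; 21 rows are filled in all 6 libraries.

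The first comparison asked which cytosines differed in methylation between the Si and NC libraries. The level at position 48 of the initiator tRNA, tRNA-iMet-CAT-1-1, which starts protein synthesis, fell in Si. It was 81.1% ± 0.991 in NC and 68.7% ± 3.46 in Si (SD, n = 3 each). The NC libraries gave 81.6%, 81.8% and 80.0% over 201, 176 and 210 reads, and the Si libraries 66.3%, 67.0% and 72.6% over 92, 91 and 95 reads, so every Si library lay below every NC library. The site is at chromosome 1, 153671296, in the tRNA gene TRX-CAT1-1 (153671250 to 153671321, plus strand), one of 8 gene copies with this sequence in the files. Of 31 tested sites, 21 were lower and 10 higher in Si by the fit. Neighbouring sites share reads, so these are not 31 independent tests. The 10 higher ones include positions 27, 28, 29 and 31 of tRNA-Asp-GTC-2-5. These lie near the lowest listed level, where a fall would leave a site unlisted. Past the adjusted threshold of 0.05 lay 1 lower site, that of tRNA-iMet, and 0 higher ones. Both of the 2 sites with an unadjusted p under 0.05 were lower in Si. The log2 odds ratio of the tRNA-iMet site, Si against NC, was -0.97, with an adjusted p of 0.00214 from edgeR's quasi-likelihood test. No standard error is given, since the one implied by edgeR's F statistic was smaller than counting error allows. The call of this single site depends on the test. It was lost under 4 of 13 alternatives that changed the fit, of which 2 that kept it were chosen after seeing the data. Fisher's exact test on summed reads, which ignores the spread between libraries, gave 1 site. Its unadjusted p at the tRNA-iMet site was 8.92e-05, close to 6.89e-05 from edgeR's test. The edgeR p was thus about what counting error alone gives. limma and quasi-binomial regression, which use the spread between libraries, gave 0 sites. Without NC replicate 2 the count was also 0, and the adjusted p at this site was 0.0518, within a range of 0.00145 to 0.17 over those 13.

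Besides tRNA-iMet, 1 other site had an unadjusted p under 0.05. This was position 38 of tRNA-Asp-GTC-1-1, a cytosine of the anticodon loop that is a known target of the methyltransferase TRDMT1. It averaged 29.8% ± 3.87 in NC and 16.6% ± 3.18 in Si (SD, n = 3) over 31 to 43 reads, with an adjusted p of 0.365 in the edgeR test, and did not pass. It lies at chromosome 12, 98503540, in TRD-GTC1-1. Position 49 of tRNA-His-GTG-1-4 averaged 89.0% ± 4.78 in NC and 78.9% ± 6.09 in Si (SD, n = 3), with an adjusted p of 0.773. At position 49 of tRNA-Gly-GCC-2-1 the levels were 77.9% ± 3.23 and 72.6% ± 3.61, and at position 50 they were 66.3% ± 8.35 and 58.6% ± 7.96 (SD, n = 3, NC then Si). Position 49 of tRNA-Asp-GTC-1-1 went the other way, with 86.7% ± 3.24 in NC and 92.3% ± 4.16 in Si (SD, n = 3), and did not pass. Among the 21 sites listed in all 6 libraries, 2 had groups that did not overlap, where chance gives 10% of sites, or 2.1.

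**Figure D2:**
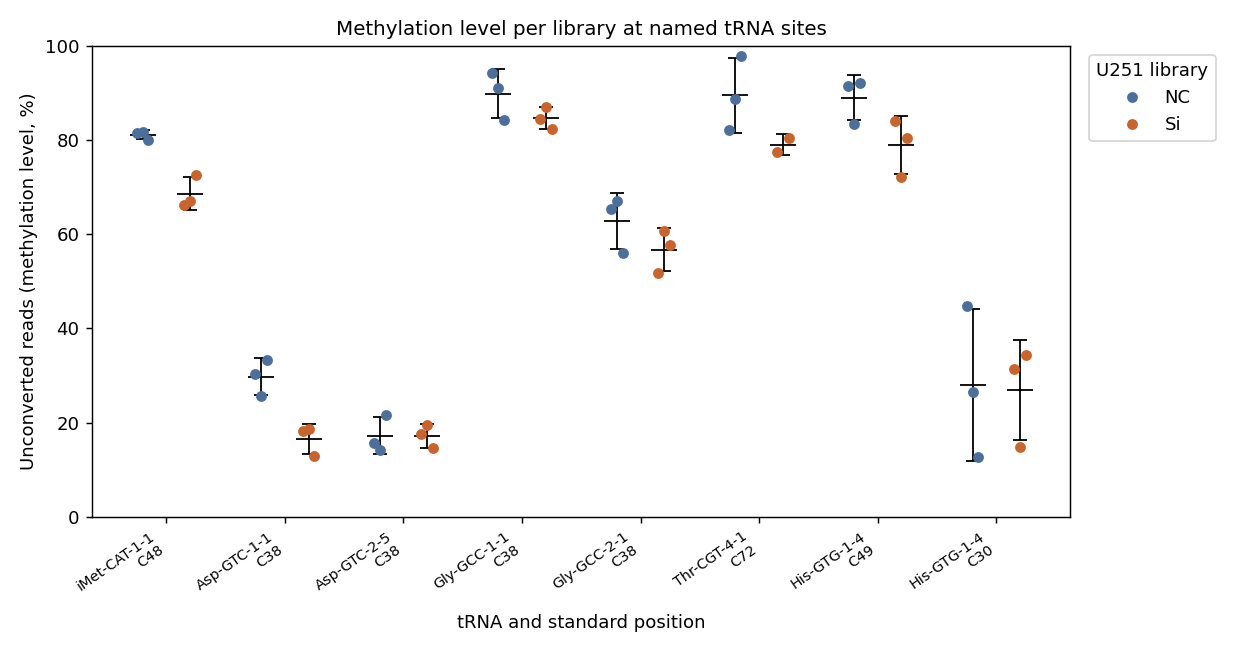
Methylation level in percent (vertical axis) of 8 tRNA sites (horizontal axis), with 1 point per U251 library, a horizontal mark at the group mean and bars of 1 SD. At tRNA-iMet-CAT-1-1 position 48 the NC points lie between 80.0% and 81.8% and the Si points between 66.3% and 72.6%; tRNA-His-GTG-1-4 position 30 runs from 12.7% to 44.8% within NC.

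The sites were next grouped by the enzyme known to make them. At position 38, the TRDMT1 class, the mean over its 4 members was 49.9% ± 1.39 in NC and 43.8% ± 2.40 in Si (SD, n = 3). tRNA-Gly-GCC-1-1 had 89.9% ± 5.17 in NC and 84.7% ± 2.38 in Si, and tRNA-Gly-GCC-2-1 had 62.8% ± 6.02 and 56.7% ± 4.58 (SD, n = 3). tRNA-Asp-GTC-2-5 had 17.2% ± 3.90 and 17.2% ± 2.51 (SD, n = 3), with a log2 odds ratio of -0.0069 whose sign changed with the setting. The exact two-sided permutation p of the class mean was 0.1, the smallest that 3 libraries against 3 allow, and 0.15 after adjustment over 3 classes. No member passed the per-site test, and 0 did when adjusted over the list alone, where the lowest adjusted p was 0.0941.

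In the variable loop class, the 16 members listed in all 6 libraries averaged 78.0% ± 0.740 in NC and 76.7% ± 0.668 in Si (SD, n = 3). The exact permutation p was 0.2, and 0.2 after adjustment over the 3 classes. Of its 18 tested members, 12 had a lower and 6 a higher fitted level in Si. The tRNA-iMet site was the 1 that passed, over all sites and when adjusted over the list alone. Position 72 of threonine tRNAs, the class of NSUN6, had 1 tested member, tRNA-Thr-CGT-4-1, at 89.5% ± 7.95 in NC (SD, n = 3) and 79.0% ± 2.22 in Si (SD, n = 2) over 31 to 47 reads. Its adjusted p in the edgeR test was 0.773, and it was unlisted in Si replicate 1. Position 40 was listed at 3 sites and could be tested at none.

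Averaged over the 21 shared sites, methylation was 70.3% ± 1.33 in NC and 68.0% ± 0.484 in Si (SD, n = 3), a difference of -2.27 percentage points. All 3 Si libraries (68.1%, 68.5% and 67.5%) lay below all 3 NC libraries (71.8%, 69.5% and 69.5%). The exact permutation p was 0.1, again the smallest possible, so this design could not have passed a threshold of 0.05. The difference was -1.50 points without NC replicate 1 and -3.95 over sites of at least 40 reads. Weighting sites by each library's own coverage gave -1.25 (exact permutation p = 0.5), a value that changes in coverage between the groups also move. Differences at single shared sites ran from -13.2 points at tRNA-Asp-GTC-1-1 position 38 to 7.75 at tRNA-Thr-CGT-4-1 position 48. Large falls at tRNA-iMet position 48 (-12.5) and tRNA-His-GTG-1-4 position 49 (-10.1) also weigh on the mean. Whether the shift is even across sites was not tested, and counting error alone spreads such differences. All listed sites belong to cytosolic tRNAs, so this mean is also that of the cytosolic class. Si libraries listed 38.3 ± 0.577 sites and NC libraries 39.7 ± 6.66 (SD, n = 3; exact permutation p = 1.0). Without NC replicate 1 the difference in listed sites turned from -1.33 to 2.33.

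Some tRNAs were listed in 1 group alone. Positions 48 and 72 of tRNA-Thr-CGT-2-1 (chromosome 16, 14285893 to 14285964) were listed in every NC library and no Si library, at 95.5% ± 1.60 and 22.6% ± 8.60 (SD, n = 3). Positions 49 and 50 of tRNA-Gly-CCC-2-2 (chromosome 16, 636736 to 636806) were listed in every Si library and no NC library, at 80.8% ± 4.89 and 83.2% ± 1.86 (SD, n = 3). Coverage at these sites was 30 to 41 reads, close to the lowest listed coverage of 30. These 4 sites compare with a mean of 0.667 over the other 9 ways of dividing the 6 libraries, and with 4 in the division of NC replicate 1, Si replicate 1 and Si replicate 3 against the rest. Fisher's exact test of presence cannot go below 0.1 for a single site.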

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

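All tests in this part were chosen after the values were seen. Groups of 3 libraries are too small for a search for outlying libraries. Sites that entered no comparison and that had a pooled level of at least 20% in at least 2 libraries were looked at again. The lists hold no site under 10.0%, so such levels do not set methylation apart from incomplete conversion. They are given as methylated reads over all reads with exact binomial 95% intervals for counting error.

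Position 48 of tRNA-Ser-TGA-1-1 had 91.8% (56 of 61 reads, 81.9% to 97.3%) in 2 NC libraries, and position 48 of tRNA-Leu-CAA-4-1 had 77.2% (71 of 92 reads, 67.2% to 85.3%) in 3 libraries. Position 72 of tRNA-His-GTG-1-4 had 58.6% (92 of 157 reads, 50.5% to 66.4%) in 3 NC libraries and 1 Si library. In tRNA-SeC-TCA-1-1, the tRNA for selenocysteine, base 41 had 39.0% (30 of 77 reads, 28.0% to 50.8%) in 2 libraries and base 42 had 30.9% (34 of 110 reads, 22.4% to 40.4%) in 3. At base 42 the level was 41.2% in NC replicate 1, 14.3% in Si replicate 1 and 36.6% in Si replicate 3. The pooled interval does not cover that spread between libraries.

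Levels in the stem of tRNA-His-GTG-1-4 and the listing of tRNA-SeC-TCA-1-1 varied between libraries of 1 group. Position 30 of tRNA-His ran through 44.8%, 26.4% and 12.7% in NC and 31.4%, 14.8% and 34.4% in Si, and the same libraries listed 8, 1 and 0 and then 4, 1 and 9 of the 10 tRNA-SeC sites. This spread lies within groups, and the difference between them, Si minus NC, was -1.07 ± 11.1 percentage points (SE); no biological explanation was tested. A conversion step that differs between libraries may be involved: the 2 measures went together over the 6 libraries (Spearman's rho = 0.93, exact permutation p = 0.0167, adjusted 0.0333; Pearson's r = 0.87, exact permutation p = 0.0306, adjusted 0.0611; r = 0.77 without the 2 libraries farthest from the median), with too few libraries to test within a group. The sites listed at positions 27 to 32 of tRNA-Asp-GTC-2-5, all near the lowest listed level, showed no such relation (rho = -0.031, exact permutation p = 1.0, adjusted 1.0, and r = -0.12, exact permutation p = 0.867). Conversion therefore stays open, as does coverage of tRNA-SeC, which also decides what is listed.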

How the results depend on the processing

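The coverage minimums of 40 reads, the test of the fixed classes only, the block for class means and all settings for coverage per tRNA were chosen after seeing the data. The count of 1 changed site became 0 with quasi-binomial regression, 0 with limma and 0 with the replicate block, and ran from 0 to 1 when each library was left out; the cause was not tested. Minimums of 1 and 30 reads removed no site, so they test nothing and are left out of the counts that follow. Over 13 alternatives the log2 odds ratio of the tRNA-iMet site stayed negative, from -1.10 to -0.89, its adjusted p ran from 0.00145 to 0.17, and 9 passed, Fisher's exact test among them, which covers counting error only. The difference in mean level moved from -2.27 to -3.95 percentage points with sites of at least 40 reads, which uses fewer sites. It was -1.25 with each library's own coverage as weights, which lets changes in coverage enter. The median over sites gave -1.73 (exact permutation p = 0.6), and leaving out a library gave -2.68 to -1.50 for the mean. For the other named sites, 164 of 171 values kept their direction and stayed past no threshold, but their sizes were loose: leaving out a library moved 27 of 80 by over 1.5 times without a change of sign, at 12 of 14 sites. tRNA-Thr-CGT-4-1 position 72 ran from -1.88 to -0.65, tRNA-Gly-GCC-1-1 position 38 from -1.21 to -0.31 and tRNA-Gly-GCC-2-1 position 50 from -0.70 to -0.19. The 7 that reversed, as log2 odds ratios, were tRNA-Asp-GTC-2-5 position 38 with limma (0.024) and 2 libraries left out in turn (-0.15 to 0.23 over all 6), tRNA-Glu-TTC-2-1 position 49 without NC replicate 1 (-0.16 to 1.10), tRNA-Gly-CCC-1-1 position 49 without Si replicate 1 (-0.89 to 0.16), and tRNA-Gly-CCC-1-1 position 50 with the replicate block (0.035) and without NC replicate 3 (-0.90 to 0.055); the cause was not tested. Same-numbered libraries share only a number: correlations of their deviations were 0.06, 0.26 and -0.38, 1 of 3 over 0.1. With the block, p of the mean level was 0.25, the smallest that 3 pairs allow, and 6 tRNAs passed in coverage. Sites listed in 1 group alone numbered 4 to 6 and tRNAs with changed coverage 4 to 6 with a library left out. With 30 to 210 reads a site, counting error limits every level.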

Other observations

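All tests in this part were chosen after the results were seen. The number of reads differed between the groups for 6 of 9 tRNAs. Relative to the 9 tRNAs compared, coverage rose in Si for tRNA-Gly-GCC-2-1 (1.81-fold), tRNA-Gly-GCC-1-1 (1.47-fold) and tRNA-Glu-TTC-2-1 (1.42-fold), and fell for tRNA-iMet-CAT-1-1 (0.538-fold), tRNA-Thr-CGT-4-1 (0.685-fold) and tRNA-His-GTG-1-4 (0.798-fold). In reads, tRNA-iMet went from 196 ± 17.6 in NC to 92.7 ± 2.08 in Si, and tRNA-Gly-GCC-2-1 from 86.3 ± 3.79 to 138 ± 17.7 (SD, n = 3). The adjusted p from edgeR was 1.37e-07 for tRNA-iMet, 4.62e-07 for tRNA-Gly-GCC-2-1, 0.000845 for tRNA-Gly-GCC-1-1, 0.00152 for tRNA-Glu, 0.00367 for tRNA-Thr and 0.0411 for tRNA-His. The other 3 tRNAs, tRNA-Asp-GTC-1-1, tRNA-Asp-GTC-2-5 and tRNA-Gly-CCC-1-1, did not pass.

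Under 11 alternative settings, tRNA-iMet, both tRNA-Gly-GCC and tRNA-Glu passed with the same direction in 11, tRNA-Thr in 10 and tRNA-His in 6. Without Si replicate 1 the adjusted p of tRNA-Thr was 0.0768; that of tRNA-His was 0.276 without NC replicate 1, 0.152 without NC replicate 2, 0.148, 0.124 and 0.0599 without Si replicates 1, 2 and 3. With the site of lowest coverage standing for each tRNA, the fall of tRNA-His was 0.486-fold, beside 0.547-fold for tRNA-iMet. Leaving out the scaling shifted the log2 ratios by a median of -0.18 and gave 3 higher and 4 lower tRNAs, with tRNA-Asp-GTC-1-1 added. The real division of the libraries gave 6 tRNAs and the highest of the others 0; 1 of 10 divisions gave as many, and 10 are too few for a share under 0.05. These are reads over filtered sites after size selection, AlkB treatment and bisulfite, so they do not measure tRNA abundance alone. Along tRNA-His-GTG-1-4, coverage at position 48 relative to position 30 was 1.07 ± 0.161 in NC and 0.628 ± 0.0279 in Si (SD, n = 3; exact permutation p = 0.1, the smallest possible, and 0.25 adjusted over 5 tRNAs). In tRNA-Asp-GTC-1-1 the ratio of position 49 to position 38 was 1.24 ± 0.0498 in NC and 0.971 ± 0.0774 in Si (SD, n = 3; exact permutation p = 0.1, adjusted 0.25). The differences in the other 3, tRNA-Asp-GTC-2-5, tRNA-Gly-GCC-1-1 and tRNA-Gly-GCC-2-1, were 0.048, 0.0039 and -0.015.

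The lower level at position 48 of tRNA-iMet was set against technical explanations. Lower conversion across the whole NC libraries is argued against: it would need an added unconverted share of 39.8% ± 6.63 (SE) at this site, while the other 20 shared sites imply 5.48% ± 2.76 (SE). The test takes the same share at every site, so it does not cover conversion that differs between tRNAs, which stays open. That lower coverage lowers the measured level stays open, since Spearman's rho of the changes across 9 tRNAs, which are not independent replicates, was 0.30 (exact permutation p = 0.437; Pearson's r = 0.47, exact permutation p = 0.198). The real division gave 1 site past the threshold and the highest of the others 0; 1 of 10 divisions gave as many, too few for a share under 0.05. An effect of the knockdown stays open as a hypothesis, and its known target was unlisted.

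Sites listed in 1 group alone could reflect the lowest listed coverage of 30 reads. From the Si to NC ratio of 0.603 at tRNA-Thr-CGT-4-1, position 48 of tRNA-Thr-CGT-2-1 would have 22.3 reads in Si, where it was unlisted. The same reckoning from tRNA-Gly-CCC-1-1 gives 39.7 reads for position 49 of tRNA-Gly-CCC-2-2 in NC, above that minimum. With counting SDs of 4.72 and 6.30 reads for a single library, both lie within 2 SDs of 30, though not within 1. Each position was missing from every library of a group, which the SD of a single library does not judge. Both expected values also borrow the ratio of a related tRNA, whose error these SDs leave out. This reckoning therefore cannot tell coverage and methylation apart. For methylation alone to unlist these 2 positions, their level would have to lie under 10.0% in each library without them. In the other group it was 95.5% for tRNA-Thr and 80.8% for tRNA-Gly. The largest difference at a tested site was -13.2 percentage points, at position 38 of tRNA-Asp-GTC-1-1. The division that gave as many such sites was NC replicate 1 and Si replicates 1 and 3 against the rest. Bases 15, 37 and 42 of tRNA-SeC and position 48 of tRNA-Leu-CAA-4-1 made up its count. It puts together the 3 libraries with the most tRNA-SeC sites, but that link is built into the count and is no separate observation.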
